A study of Mus musculus with 6 samples.

How the data were processed

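Gene expression was measured by RNA sequencing in cultured mouse bone marrow-derived macrophages of 2 genotypes, with 3 libraries each. Wild-type (WT) cells came from C57BL/6J mice. Per the labels, knockout cells came from mice with loxP-flanked Rxra alleles, Cre recombinase expressed from the lysozyme M locus (Lyz2) and inactivated Rxrb alleles. Rxra and Rxrb encode the retinoid X receptors alpha and beta, nuclear receptors that pair with many other nuclear receptors. Marrow precursors were grown for 6 days with medium conditioned by L929 cells, a source of the macrophage growth factor CSF-1. The cells then received serum-free medium and the solvent DMSO for 3 hours, so no library was activated with a ligand. The labels call the replicates biological and do not say from which animals each came, so the p-values measure the spread between these libraries.

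Libraries were made from 100 ng of RNA with the NEBNext Ultra II kit and read single-end on an Illumina NextSeq with a kit of 75 cycles, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.7, DESeq and the mouse build mm10 (GRCm38). The counting program, the annotation release and whether strand was used are not given in the sources used here. Reads of overlapping genes and of near-identical copies can therefore be split or misplaced. Some genes at risk are named as uncertain, but a gene without this mark is not thereby free of the risk. The authors deposited a table of raw counts per Ensembl gene, whole numbers for 45193 genes, and this table was used for the main tests. A second table holds log2 values that the authors normalized. Set against the counts, each of its columns is the log2 of the count times a constant, between 1.08 and 1.09 times the inverse of the median-of-ratios size factor. In the knockout columns a count of 1 stands as 0, because the factor there is below 1. This affects 3522, 2422 and 2852 genes in knockout replicates 1, 2 and 3 and none in the WT columns. No column of per-sample values was left unused.

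Counts were tested with edgeR 4.0.16 (R 4.3.3) by its robust quasi-likelihood F test with TMM factors, on 12011 genes kept by filterByExpr with the group as its design (minimum count 10, minimum total count 15). The model held the genotype alone. P-values were adjusted by the Benjamini-Hochberg method over the tested genes with a threshold of 0.05. Each SE is the absolute log2 fold change divided by the square root of the F statistic. It therefore restates the F test and is not a separate estimate of precision. Levels are given as TMM-scaled CPM (counts scaled to a common library total), mean ± SD over 3 libraries. Gene symbols were matched by Ensembl identifier for 45106 of the 45193 genes. Positions, transcript lengths and GC content came from the GENCODE M21 annotation of GRCm38.

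Gene lists for nuclear receptors and their targets, lipid metabolism, growth factors, inflammation, macrophage functions, cell cycle, stress responses, other cell types, sex and the modified loci were fixed before the data were examined, as were the tests, the first set of alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over 28 lists. Camera with an estimated correlation and fry were the alternatives. Some genes stand in several lists, so results of such lists are not independent. Nr1h3 is both a nuclear receptor and an LXR target. Tgm2 is in the PPAR target, retinoic acid receptor target and alternative activation lists. Mmp9 is in the matrix, osteoclast and neutrophil lists, and Atp6v0d2 in the lysosomal and osteoclast lists. Mitochondrially encoded transcripts were not analysed here. Genes were named by these parts of the rule. The first was Rxra, Rxrb, Rxrg, Gdf15 and Lyz2. The second was the 10 highest and 10 lowest log2 fold changes past the threshold with non-overlapping groups and an average log2 CPM of at least 2, without predicted models, clones and pseudogenes. The last was the members of each list with the smallest adjusted p, up to 3 that rose and 3 that fell in the lists closest to the study's question and up to 2 and 2 in the others. For a list with no member past the threshold, and for each list of cell type or locus markers, the most abundant member was also taken. The rule gave 113 genes, of which some are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

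Alternatives fixed at the same time were the RLE and upper-quartile factors, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on the authors' log2 values, the replicate number as a block, and leaving out each library in turn. For the limma fit, the authors' log2 values were turned back to the linear scale, with those at 0 taken as 0, and tested as log2(linear value + 1). Alternatives added after seeing the data were libraries thinned to the smallest total, offsets for transcript length and GC content fitted by loess (span 0.5) in each library, leaving out X-linked and Y-linked genes, leaving out genes within 10 Mb of the modified loci, leaving Rxrb and Lyz2 out of the lists, and camera with an estimated correlation together with the offsets. The steps were tested on simulated data with 200 changed genes, 50 at each fold, and a further list of genes lowered 1.5-fold. Means and library sizes were those of this comparison. Of 11872 simulated genes run, edgeR recovered 35 of 50 at 1.5-fold, 42 at 2-fold, 49 at 4-fold and 49 at 8-fold, and 9.68% of its calls were false, above the nominal rate. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).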

Results

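Messenger RNA was profiled in unstimulated bone marrow-derived macrophages, cells grown from mouse marrow with CSF-1, of WT and RXR alpha and beta knockout mice. The series title concerns macrophages that express growth factors, GDF-15 among them. The comparison asks which transcripts differ between the genotypes before any activation. Total counts were 9642889, 7880320 and 14957253 in WT replicates 1, 2 and 3, and 17250051, 25091019 and 18491943 in knockout replicates 1, 2 and 3. The knockout mean was 1.87 times the WT mean (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow), so depth and genotype cannot be separated by design. Correlations of log2 CPM ranged from 0.985 to 0.989 within WT, from 0.988 to 0.994 within the knockout and from 0.968 to 0.979 between them. The first principal component carried 57.3% of the variance and separated the genotypes.

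The targeted genes were examined first. Rxrb (ENSMUSG00000039656, chromosome 17, 34031812 to 34038399 in GRCm38) fell from 66.7 ± 1.86 CPM in WT to 9.27 ± 2.09 CPM in the knockout (SD, n = 3), a log2 fold change of -2.85 (SE 0.138, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 4.54e-08). Rxra (ENSMUSG00000015846, chromosome 2, 27676440 to 27762957) stood at 104 ± 6.7 CPM in WT and 109 ± 4.83 CPM in the knockout, a log2 fold change of 0.07 (SE 0.083, edgeR adjusted p = 0.588). Its sign turned with offsets for transcript length and GC content (-0.069), again short of the threshold. Counts over the whole gene do not check the removal of the part of Rxra between loxP sites, so they neither support nor contradict the Rxra label. Lyz2, the lysozyme gene whose locus carries Cre per the labels, fell from 15300 ± 594 CPM to 28.4 ± 6.12 CPM (log2 fold change -9.07, edgeR adjusted p = 3.07e-12), 0.19% of the WT level. Its near-identical neighbour Lyz1 rose from 15 ± 0.718 to 63.3 ± 12.9 CPM. Reads can be shared between the copies, so the Lyz1 levels and the residual Lyz2 level in the knockout are uncertain. Lyz2 reads placed on Lyz1 would mostly raise its WT level, which would make this rise smaller, not larger. Rxrg, the remaining family member, had 0 reads in each WT library and 1, 0 and 4 reads in knockout replicates 1, 2 and 3, too few for a test. No Cre or change of Lyz2 is described for the WT cells. Effects of RXR loss, Lyz2 loss and Cre therefore cannot be separated in any difference reported here.

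**Figure D1:**
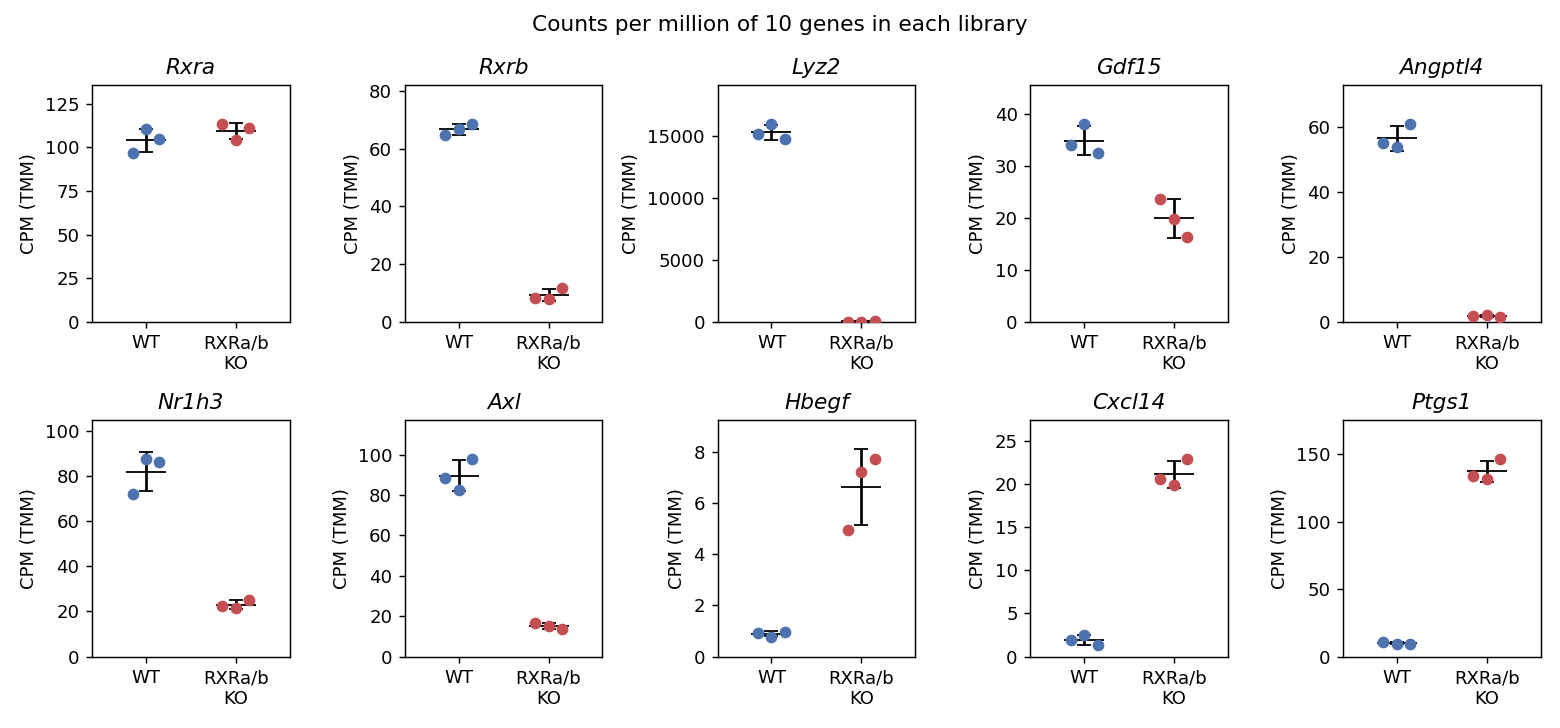
Each panel plots TMM-scaled CPM of a gene (vertical axis, from 0) in the 3 WT (blue) and 3 knockout (red) libraries; points are libraries, long bars are means and whiskers are SD. Rxrb lies at 66.7 CPM in WT and 9.27 CPM in the knockout, while the points of Rxra overlap between the genotypes.

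Knockout macrophages differed from WT in 2327 of 12011 tested genes, 1173 higher and 1154 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 389 of these differed at least 2-fold, 231 higher and 158 lower. Among the highest were Ptgs1, the cyclooxygenase COX-1, which rose from 9.83 ± 0.787 to 137 ± 7.91 CPM (log2 fold change 3.81, SE 0.105), and Il21r, the receptor of interleukin 21 (3.55, SE 0.129). The chemokine gene Cxcl14 (3.54, SE 0.189), the EGF-family ligand gene Hbegf (2.85, SE 0.275) and Nes, which encodes the intermediate filament nestin (2.82, SE 0.161), also rose. Enpp4 (3.09), Tnfrsf10b (3.07) and Cmah (2.83) completed the rule's top group, together with Xist, described further on, and Hmga1b. Hmga1b rose from 2.22 to 39.4 CPM while Hmga1, of which it is a near-identical copy, fell from 130 to 73.4 CPM. Hmga1 was chosen after its values were seen, and both are uncertain because of shared reads. Among the lowest after Lyz2 were Angptl4, an inhibitor of lipoprotein lipase (56.4 ± 3.76 to 1.88 ± 0.286 CPM, log2 fold change -4.89, SE 0.14), and the organic anion transporter gene Slco2b1 (-4.08). The C-type lectin genes Clec4b1 (-3.34) and Clec10a (-2.81), the hydrolase gene Cmbl (-2.94), Noct, which encodes nocturnin (-2.81), the adhesion molecule gene Vcam1 (-2.72) and the kinase gene Sik1 (-2.70) fell as well. Angptl4 and Sik1 lie within 10 Mb of Rxrb, and Ptgs1 lies within 10 Mb of Rxra. All 3 values of each genotype lay apart from the other's in 4429 genes, 36.9% of those tested, where chance gives 10%. Leaving out WT replicate 1 lowered the count of changed genes to 1286, and leaving out knockout replicate 1 lowered it to 1383. Leaving out WT replicate 3 raised it to 2607.

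Genes of the receptors that pair with RXR moved in both directions. Of 13 tested nuclear receptor genes, 1 rose, 3 fell and 9 did not pass the test, with the same counts adjusted over the list alone. Nr1h3, which encodes the oxysterol receptor LXR alpha, fell from 81.8 ± 8.66 to 23 ± 1.95 CPM (log2 fold change -1.83, SE 0.107), and Rarg, a retinoic acid receptor gene, rose from 20 ± 1.22 to 37.5 ± 1.03 CPM (0.90, SE 0.101). The other 2 that fell were Rxrb itself and Nr4a1 (-0.62), whose call was lost when any library was left out. As a set the list missed the threshold (camera adjusted p = 0.0584, and 0.527 with an estimated correlation). It holds Rxrb, so its downward direction is partly fixed by the genotype. It passed without WT replicate 1 (0.0131), WT replicate 2 (0.034) or knockout replicate 3 (0.0181), with the length and GC offsets (0.00701), after thinning (0.0298), and with no filter (0.0101) or the CPM filter (0.0498). With Rxrb left out of the list, a step chosen after seeing the data, camera's adjusted p was 0.64, and from 0.401 to 0.926 in the other fits tested this way, so those calls rested on Rxrb. The mean went from -0.252 to -0.0354 and the median from 0.073 to 0.0814.

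LXR target genes were split. Of 22 tested, 5 rose, 6 fell and 11 did not pass (6 and 7 adjusted over the list alone), and the set test did not call the list (camera adjusted p = 0.359). The cholesterol exporter gene Abca1 rose from 277 ± 34.6 to 536 ± 17.1 CPM (log2 fold change 0.95, SE 0.094), as did the fatty acid desaturase gene Scd2 (1.29, SE 0.098) and Smpdl3a (0.49, SE 0.089). Cd5l, a secreted inhibitor of apoptosis, fell from 1010 ± 27 to 423 ± 12 CPM (-1.25, SE 0.075), and Mylip, a ubiquitin ligase gene, fell from 64.1 to 29.8 CPM (-1.11, SE 0.117). The list's median was 0.0135 and its mean -0.0624, and 3 members rose without WT replicate 1 or without knockout replicate 1. Of 6 tested retinoic acid receptor targets, Dhrs3 rose (0.41) and Tgm2 (-0.64) and Asb2 (-1.61) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.476). Asb2 had 45 and 26 reads over the 3 libraries of each genotype and lost its call without WT replicate 1, WT replicate 3 or knockout replicate 2.

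Targets of PPAR receptors, which regulate lipid storage and breakdown with RXR, were lower. Of 20 tested, 13 fell, 1 rose and 6 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.42, camera adjusted p = 8.85e-14). With an estimated correlation the set test gave an adjusted p = 0.108. Beside Angptl4, the lipid droplet coat gene Plin2 fell from 1700 ± 65.5 to 718 ± 20.8 CPM (-1.25, SE 0.076) and Hadhb, a subunit of the mitochondrial trifunctional protein, fell from 58.4 ± 4.8 to 27.2 ± 3.13 CPM (-1.10, SE 0.109). The fatty acid-binding protein gene Fabp5 was the member that rose (0.36), and its call was lost without WT replicate 1 or 2 or knockout replicate 1 or 2. Of 22 fatty acid oxidation genes, 9 fell (10 adjusted over the list alone), 0 rose and 13 did not pass (median -0.21, camera adjusted p = 5.7e-04, and adjusted p = 0.108 with an estimated correlation). The correlation estimated for that list, 0.00552, lay below the preset 0.01, so a larger correlation does not explain this loss of the call. Cpt1a, which controls entry of fatty acids into mitochondria, fell from 223 ± 19.2 to 118 ± 11.8 CPM (-0.92, SE 0.096). Several genes, Cpt1a and Hadhb among them, belong to both lists, so these are not independent results.

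Genes of cholesterol synthesis and uptake that passed the test were all higher, but most did not pass. Of 24 tested, 6 rose, 0 fell and 18 did not pass, with the same counts adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.0145). The set call was lost with an estimated correlation (adjusted p = 0.483) and without WT replicate 3 (adjusted p = 0.118). Insig1, a sterol-regulated brake on this pathway, rose (0.68, SE 0.104), as did Srebf2, which encodes its main transcription factor (0.42, SE 0.085); both were chosen after their values were seen.

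Growth factor genes moved in both directions. Gdf15, the gene named in the series title, fell from 34.8 ± 2.8 to 19.9 ± 3.69 CPM (SD, n = 3), a log2 fold change of -0.81 (SE 0.135, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.00115), and every knockout library lay below every WT library. The anti-inflammatory cytokine gene Il10 fell from 11.5 ± 2.43 to 3.49 ± 0.683 CPM (-1.74, SE 0.201), and Pdgfc fell (-1.30, SE 0.353). Hbegf rose from 0.899 ± 0.103 to 6.63 ± 1.48 CPM, Gdf3, of the TGF-beta superfamily, from 18 ± 2.98 to 43 ± 0.0863 CPM (1.28) and Pdgfb from 157 ± 6.78 to 241 ± 10.8 CPM (0.62). Of 24 tested growth factor genes 8 rose, 3 fell and 13 did not pass (10 and 4 adjusted over the list alone), and the set test missed the threshold (camera adjusted p = 0.122, and 0.444 with an estimated correlation), which it passed with the length and GC offsets (0.0123). Fry called the growth factor list in the upward direction (adjusted p = 0.0134). Without knockout replicate 1, 5 rose. The call of Pdgfc was lost without WT replicate 1 or 3 or knockout replicate 1 or 2.

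Chemokine genes were higher. Of 16 tested, 7 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 1.35e-05, and adjusted p = 0.108 with an estimated correlation). Cxcl14 rose from 1.91 ± 0.554 to 21.1 ± 1.54 CPM, Ccl4, an attractant of monocytes and lymphocytes, from 29.3 ± 2.75 to 73.9 ± 1.44 CPM (1.34, SE 0.096) and Ccl2, the main monocyte attractant, from 4.76 ± 0.561 to 16.8 ± 0.876 CPM (1.84, SE 0.147). Ccl22 fell (-1.40, SE 0.408) on 43 and 31 reads, a call that was lost when any library other than WT replicate 3 was left out; without WT replicate 3, 2 chemokine genes fell. NF-kB inflammatory genes went both ways, with 7 that rose, 5 that fell and 13 that did not pass of 25 (the same adjusted over the list alone). Several members, Ccl2 and Ccl4 among those that rose, also belong to the chemokine list, so these are not independent results. The adhesion molecule gene Icam1 (-0.75) and the NF-kB inhibitor gene Nfkbia (-0.49) fell. The set test did not call the NF-kB list (camera adjusted p = 0.19, and 0.569 with an estimated correlation, median -0.0369, mean 0.254). It passed with the length and GC offsets (0.0383), but not with the offsets and an estimated correlation together (0.501). Of 38 interferon-stimulated genes 5 rose, 0 fell and 33 did not pass (the same adjusted over the list alone, camera adjusted p = 0.127), with Gbp2 (0.91) and Rsad2 (0.75) as examples. Without WT replicate 1, 2 of them rose, and without WT replicate 3, 1 fell. The interferon list passed with the length and GC offsets (0.0383) and with no filter (0.0395). It did not pass with an estimated correlation (0.569) or with that and the offsets together (0.536).

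Macrophage surface and clearance genes moved in both directions. Of 23 genes of efferocytosis, the uptake of dying cells, 6 rose, 6 fell and 11 did not pass (7 and 6 adjusted over the list alone, camera adjusted p = 0.502). The receptor kinase gene Axl fell from 89.5 ± 7.63 to 15.2 ± 1.45 CPM (-2.56, SE 0.107) and the integrin gene Itgav from 224 ± 5.64 to 102 ± 7.45 CPM (-1.15). Mfge8, which bridges dying cells to integrins, rose from 121 ± 7.9 to 359 ± 21.3 CPM (1.57, SE 0.085), and the scavenger receptor gene Stab1 rose from 1240 ± 167 to 2970 ± 143 CPM (1.26), with an uncertain part because it overlaps Nt5dc2 on the other strand. Of 15 alternative activation genes 7 rose, 5 fell and 3 did not pass (the same adjusted over the list alone, camera adjusted p = 0.797, median 0.146, mean -0.123). Clec7a, the beta-glucan receptor gene, rose (0.83) and so did the interleukin 4 receptor gene Il4ra (0.57), while Clec10a fell from 28.3 ± 6.4 to 4.01 ± 0.483 CPM. Without WT replicate 1, 3 of them rose and 3 fell; 4 rose without WT replicate 3, and 3 fell without knockout replicate 1. Of 20 macrophage identity genes 5 rose, 4 fell and 11 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.0707). Its set call appeared without WT replicate 2 (0.0167) or knockout replicate 2 (0.0301) and with no filter (8.4e-05), but the list holds Lyz2, and without that gene, left out after seeing the data, these became 0.674, 0.71 and 0.626. Cd14 (296 ± 11.2 to 628 ± 34 CPM, 1.09) and Irf8 (0.63) rose and Aif1 (-0.72) fell.

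Lysosomal genes included the glucosidase gene Gaa (0.96), which rose, and Scarb2 (-0.64) and Atp6v0d2 (-0.70), which fell. Of 38 tested 6 rose, 4 fell and 28 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.558). Of 14 osteoclast genes 6 rose, 4 fell and 4 did not pass (6 and 5 adjusted over the list alone, camera adjusted p = 0.502), with Dcstamp, needed for cell fusion, higher (0.69) and the chloride transporter gene Clcn7 lower (-0.59). Matrix and protease genes gave 8 that rose, 6 that fell and 11 that did not pass of 25 (10 and 6 adjusted over the list alone, camera adjusted p = 0.731, median 0.0272, mean -0.178). Among them Mmp9 (1.54) and Thbs1 (1.04) rose, and Col4a2 (-3.14) and Mmp14 (-1.52) fell, and 5 members rose without knockout replicate 1 or without knockout replicate 2. Of 13 genes of antigen presentation by MHC class II, Cd86 (0.65) and Cd40 (0.43) rose, 3 fell, H2-Ab1 (-0.54) and H2-Eb1 (-0.46) among them, and 8 did not pass (2 and 4 adjusted over the list alone, camera adjusted p = 0.472). Both rises are fragile: Cd86 lost its call without WT replicate 1 or 3 or knockout replicate 1 or 2, and Cd40 lost it when any library other than knockout replicate 3 was left out. With the length and GC offsets 4 rose.

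**Figure D2:**
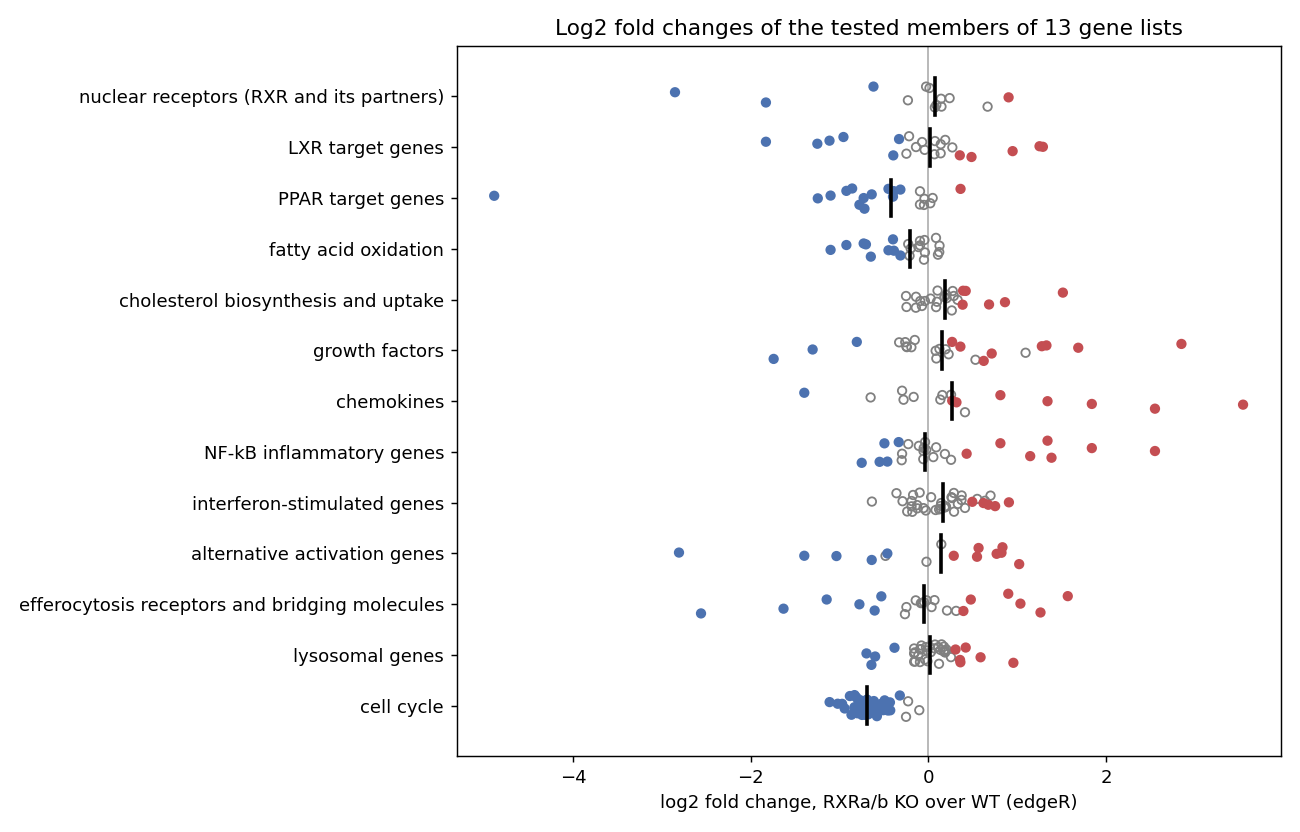
Log2 fold changes of the knockout over WT from edgeR (horizontal axis) are plotted for the tested members of 13 gene lists (vertical axis, with random vertical scatter); filled red and blue points rose and fell past the threshold, open points did not pass, and black bars are medians. Cell cycle genes lie left of 0 with a median of -0.69, and PPAR targets have a median of -0.42.

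Cell cycle genes were lower almost throughout. Of 37 tested, 34 fell (36 adjusted over the list alone), 0 rose and 3 did not pass (median log2 fold change -0.69, camera adjusted p = 1.32e-27, and adjusted p = 0.108 with an estimated correlation). Birc5, which encodes the mitotic protein survivin, fell from 84.4 ± 8.11 to 41.5 ± 1.33 CPM (-1.02, SE 0.094), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 54.3 ± 6.76 to 25.1 ± 2.34 CPM (-1.11, SE 0.114). The members short of the threshold, chosen after their values were seen, were Mcm6 (-0.23), Pcna (-0.25) and E2f1 (-0.10). Between 31 and 35 members fell with each library left out in turn.

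Markers of other cell types were counted beside these groups. Of 17 neutrophil markers 4 rose, 5 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 0.731, median -0.0549, mean 0.0235). The early granule protein genes Mpo (54.3 ± 2.9 to 29.5 ± 1.81 CPM) and Elane (29.8 ± 5.33 to 13.9 ± 1.9 CPM) fell, while Mmp9 and the growth factor receptor gene Csf3r (48 ± 8.99 to 81.2 ± 9.23 CPM) rose. Chosen after their values were seen, Prtn3 (-0.83) and Ctsg (-1.27) also fell and Mmp8 (0.61) and Cxcr2 (1.19) rose. Without knockout replicate 1, 2 markers rose, and without WT replicate 1, 3 fell. Ngp, the most abundant, stood at 377 ± 19.3 and 313 ± 24.5 CPM, and its call (-0.27) was lost when any library other than WT replicate 3 was left out and with the length and GC offsets (-0.09, adjusted p = 0.48). The monocyte list was not called (camera adjusted p = 0.19, and 0.483 with an estimated correlation). It passed with no filter (0.02) and with fry (adjusted p = 0.00798). Of 11 monocyte markers 1 rose, 5 fell and 5 did not pass, the same adjusted over the list alone. Without WT replicate 1, 1 of them fell, and 2 fell without WT replicate 3 or without knockout replicate 1. Napsa fell (-0.47), Fn1 fell (-1.04) but lost its call without WT replicate 1 or 3 or knockout replicate 1, and F13a1 rose (0.36) but lost its call without WT replicate 1 or 2 or knockout replicate 1 or 2. Of 4 dendritic cell markers Itgax rose (0.52), and 2 rose adjusted over the list alone, without knockout replicate 3 or with the length and GC offsets. Of 2 B cell markers Cd79b fell (5.25 to 1.7 CPM), while Cd22 stood at 12.3 and 15.1 CPM and passed only adjusted over the list alone. None of 2 T and NK cell markers passed in either adjustment, with Cd4 at 12.5 and 10.3 CPM, nor any of 4 mast cell and basophil markers, with Hdc at 6.35 and 8.07 CPM. Epor, the tested erythroid marker, fell from 1.82 to 0.22 CPM in both adjustments. Of 7 stromal markers Kitl rose (1.12) and Col3a1 fell (-1.91), with 3 that fell adjusted over the list alone, without WT replicate 2 or without knockout replicate 3, and 2 with no filter (camera adjusted p = 0.735). Of 3 endothelial markers Kdr rose (2.22) and Stab2 fell (-1.63; list median -0.185, mean 0.134), the same adjusted over the list alone.

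Sex-specific transcripts separated the genotypes. Xist, the RNA that silences an X chromosome in female cells, had 0 reads among 32480462 in the WT libraries and 237 ± 28.9 CPM in the knockout (SD, n = 3). Set against a floor of 3 reads over the WT group, which covers counting error only, it was at least 2570-fold higher. The Y-linked genes Ddx3y (107 ± 5.6 to 51.7 ± 3.23 CPM) and Eif2s3y (66.9 ± 5.62 to 31.4 ± 2.95 CPM) fell, and the mean of 4 Y-linked genes in the knockout libraries was 53.1% ± 4.11 of the WT mean (SD, n = 3). All 5 genes of the list passed, 1 higher and 4 lower, and the same adjusted over the list alone (camera adjusted p = 0.472 in the upward direction, against a median log2 fold change of -0.80). Xist and Y-linked transcripts were both present in each knockout library, so this difference moves with genotype in every gene group above. Without X-linked and Y-linked genes 2255 genes changed, and 66 of 384 X-linked genes (17.2%, Xist left out) against 2254 of 11612 autosomal genes (19.4%) changed (two-sided Fisher's exact test over genes p = 0.294; genes are not independent replicates).

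**Figure D3:**
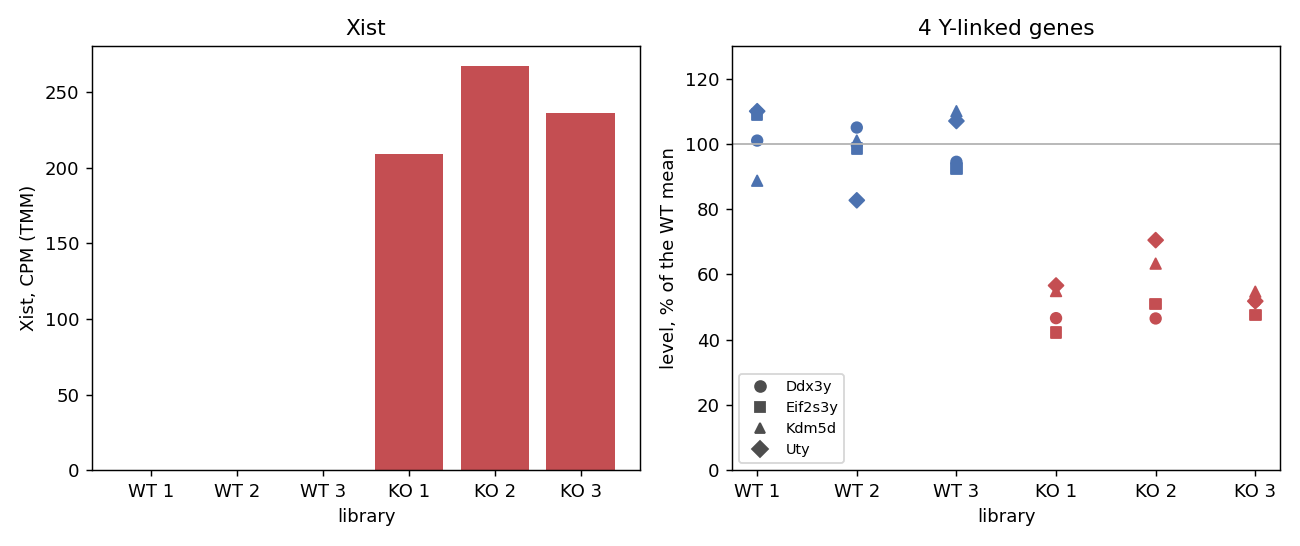
The left panel plots Xist in CPM per library (bars from 0), and the right panel plots 4 Y-linked genes per library as a percent of their WT mean (points, grey line at 100%); WT is blue and the knockout red. Xist is 0 in the WT libraries and 209, 267 and 236 CPM in knockout libraries 1, 2 and 3, where Y-linked genes average 50.1%, 57.8% and 51.5%.

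Fold changes also followed transcript length. Across 12003 genes, which are not independent replicates, Spearman's correlation of the log2 fold change with transcript length was 0.326, against 0.057 with GC content. Median log2 fold changes ran from -0.21 in 663 genes under 1000 bases to 0.22 in 626 genes over 8000 bases. Of the shortest genes 24 rose and 114 fell past the threshold, and of the longest 179 rose and 20 fell. The trend differed between libraries of the same genotype. Correlations with log2 length were -0.225, -0.207 and 5.44e-04 in WT replicates 1, 2 and 3. In knockout replicates 1, 2 and 3 they were 0.166, 0.246 and 0.0968. Short transcripts of 2 groups chosen after seeing the data moved with this trend: 46 of 76 cytosolic ribosomal protein genes and 28 of 75 respiratory chain genes fell. With offsets for length and GC content, added after seeing the data, 21 and 12 of them fell, 1953 genes changed in all, and 1671 of these were shared in the same direction. With these offsets 35 cell cycle genes, 10 PPAR targets and 7 fatty acid oxidation genes fell, and 6 cholesterol genes and 8 chemokine genes rose. With every library thinned to the smallest total 2064 genes changed.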

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

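Thinning, the length and GC offsets and the removal of X-linked and Y-linked genes or of genes near the modified loci, camera with an estimated correlation on the offsets, and lists without Rxrb and Lyz2 were chosen after the results were seen; the others were planned. Counts of changed, higher, lower and 2-fold genes stayed within 1.5 times the reported ones under all settings except the replicate block and the removal of WT replicate 1 or knockout replicate 1. The replicate numbers do not pair the libraries (correlations of deviations 0.0528, -0.275 and -0.259, and no library correlated best with its own number). WT replicate 2 and knockout replicate 3 correlated most (0.307). They also lay apart from the other libraries on the second principal component (18.5% of the variance). What they share was not tested. The replicate block gave 1375 changed, 709 higher and 666 lower genes and called 7 lists. Nuclear receptors and macrophage identity were added (both 0.047, and both 0.643 without Rxrb and Lyz2). With each library left out in turn, changed genes ranged from 1286 to 2607, higher from 667 to 1278, lower from 619 to 1329 and 2-fold from 320 to 402; without knockout replicate 1 they were 1383, 697, 686 and 354. The lowest counts came without WT replicate 1. With as few libraries, 2607 genes changed without WT replicate 3 and 2188 without knockout replicate 3. Fewer libraries alone therefore do not explain the drop, and further causes were not examined. Of the 113 named genes, 12 lost their call under the block and up to 13 with a library left out. Calls were lost under at least 1 setting for Nr4a1, Asb2, Pdgfc, Ccl22, Pfkp, Mif, Cd86, Cd40, Slc7a11, Gclm, Ngp, F13a1, Rpl7a, Fabp5, Fn1 and Mthfd2. Rxra reversed with the length and GC offsets (-0.069, adjusted p = 0.57), and the cause was not tested. Lists called numbered 10 without a filter, 9 with the offsets, 12 with fry, 0 with an estimated correlation (4 at unadjusted p under 0.05) and 2, cell cycle (0.0309) and chemokines (0.032), with both; fry's test of change in either direction called all 28. Leaving out libraries called 4 to 7, and lists without Rxrb and Lyz2 5. Fry added monocyte markers (0.00798), macrophage identity (0.0147), MHC class II (0.0177) and nuclear receptors (0.0207) in the downward direction. Upward, it added growth factors (0.0134), immediate early genes (0.0177) and the neighbours of Rxra (0.0452). It was not run without Rxrb and Lyz2, which the nuclear receptor and macrophage identity lists hold. A larger correlation does not account for every loss: the estimate for fatty acid oxidation was 0.00552, below the preset 0.01. That list's camera adjusted p still went from 5.7e-04 to 0.108. The causes of these differences between settings were not tested. The real grouping was 1 of 10 splits of the 6 libraries, too few for a share under 0.05. It gave 2327 changed, 1173 higher, 1154 lower and 389 2-fold genes and 5 lists, where the highest other split gave 0, 0, 0, 0 and 4. The other splits called 1 to 4 lists with no changed gene at the threshold; each sets libraries of both genotypes against each other unevenly, so they still carry part of the genotype difference. In the simulated comparison, edgeR missed 15 of 50 genes changed 1.5-fold, so small changes can be missed. A far smaller share of genes changed there than the 19.4% called here, which makes its adjusted threshold stricter. That miss rate therefore need not hold for these data.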

Other observations

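The tests of windows around Rxrb and Rxra, and of WT RNA in the knockout libraries, were chosen only after the results were seen. The lists of genes that escape X inactivation and of immature myeloid markers were not among the fixed lists. They were drawn up for patterns already seen. Immediate early genes, switched on within minutes of stimulation, went both ways: Egr3 (6 and 177 reads over the WT and knockout libraries) and the phosphatase gene Dusp4 (59.8 ± 1.7 to 94.8 ± 4.97 CPM) rose, while Fos (245 ± 9.74 to 121 ± 7.04 CPM) and Dusp2 (6.06 to 2.65 CPM) fell. Of 23 tested, 5 rose, 4 fell and 14 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.476). Without WT replicate 1 or without knockout replicate 1, 3 rose and 2 fell, and 2 fell without WT replicate 2, without knockout replicate 2 or after thinning. Of 25 glycolysis and hypoxia genes 5 rose, 4 fell and 16 did not pass (5 and 6 adjusted over the list alone, camera adjusted p = 0.797), with P4ha2 (0.76) and Pfkp (0.42) higher and Ldha (-0.58) and Mif (-0.72) lower. With the length and GC offsets the calls of Pfkp (adjusted p = 0.0508) and Mif (0.102) were lost and 3 members rose. Pfkp is uncertain because it overlaps Pitrm1 on the other strand. Without WT replicate 1, 3 rose and 2 fell, and 2 fell without knockout replicate 1 or without knockout replicate 3. Of 19 integrated stress response genes 1 rose, 4 fell and 14 did not pass (the same adjusted over the list alone, camera adjusted p = 0.29). The asparagine synthetase gene Asns fell (-0.63), and Mthfd2 fell (-0.44) but lost its call without WT replicate 1. Without WT replicate 1, 1 member fell, and 2 fell without knockout replicate 2 or after thinning. Of 20 NRF2 targets Slc7a11 (0.41) and Gclm (0.24) rose and 18 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.476). Slc7a11 lost its call without WT replicate 2 or 3 or knockout replicate 1 or 2, and Gclm when any library other than WT replicate 3 was left out. Both also lost it with the length and GC offsets, and 2 members fell without WT replicate 3.

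Every knockout library held Xist together with Y-linked RNA, the latter at 53.1% of the WT level on average, so cells of both sexes may have been pooled in each. Wild-type female RNA mixed in would need Lyz2 at 10% of WT or more, and Lyz2 stood at 0.19%, which argues against it. A pool of both sexes predicts higher levels of genes that escape X inactivation, and these had a median log2 fold change of 0.26, with 6 of 9 above 0, 2 past the threshold (Kdm6a and Kdm5c, chosen after their values were seen) and Ddx3x, chosen likewise, at 0.02. Sex mix and genotype cannot be separated in these libraries, so any gene that differs by sex could contribute to the reported counts, 2255 genes still differing without X-linked and Y-linked genes. No biological explanation was tested.

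Cell cycle genes were lower in the knockout, and greater depth of its libraries or a trend with length and GC content could lower them. After thinning, the list's median was -0.679 (95% order-statistic interval over genes -0.761 to -0.559), against -0.69 as deposited. Thinning keeps the expected ratios of well-counted genes, so it could hardly move this median and does not decide on depth. After the offsets the median was -0.684 (-0.744 to -0.565). These intervals take the genes as independent, which they are not. The list's median transcript length was 3421 bases, near the 3323 of all genes, so the length trend could shift it little. The trend with length and GC content therefore does not account for the whole pattern. Fewer leftover immature myeloid cells remain possible: their markers had a median of -0.0733, with 7 of 11 below 0, but Sox4 and Cdk6 (chosen after their values were seen) rose, none fell, and most others were under 5 CPM. That list left out genes whose values had been seen: Mpo (-0.88), Elane (-1.10), Prtn3 (-0.83) and Ctsg (-1.27) fell, which goes with fewer such cells, while Kit (0.51) and Gata2 (0.40) did not pass. Sex mix and the knockout genotype also stay open, as untested.

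DNA of another strain carried along with a modified allele could change genes near it. Within 10 Mb, 14 of 295 tested genes near Rxrb, 10 of 218 near Rxra and 4 of 64 near Lyz2 differed at least 2-fold. These shares lay at percentiles 83, 81.2 and 92.5 of windows elsewhere, above the median window and under the 95 set for crowding, so the test left this open. At other widths the percentiles ran from 68.5 to 87.7 for Rxrb and 57.2 to 88.1 for Rxra. For Lyz2 they ran from 73.9 to 95.6, the highest on 3 of 35 genes within 5 Mb. Lyz1, uncertain because it can share reads with Lyz2, was among the changed genes near Lyz2 and was not left out. Without genes of the H2 family, whose copies can share reads, Rxrb's percentile was 74.2, which decides nothing because crowding was not shown to begin with.

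Among the fixed lists of neighbours, 4 of 20 near Rxrb fell, Pfdn6 (-0.70) and H2-DMb1 (-0.72) among them, and 16 did not pass (the same adjusted over the list alone). Camera's adjusted p was 0.21, with 0.0264 with no filter and 0.569 with an estimated correlation. H2-K1 stood at 1100 ± 42.2 and 1190 ± 38.1 CPM. Of 15 near Rxra 3 rose, 1 fell and 11 did not pass (the same adjusted over the list alone, camera adjusted p = 0.476). Olfm1 (0.94) and Col5a1 (1.80) rose, and Rpl7a fell (-0.30), a call lost when any library other than WT replicate 3 was left out and with the length and GC offsets (-0.10). Knockout replicates 1 and 3 detected 18303 and 18996 genes after thinning, and knockout replicate 2 detected 15952, against 16400 to 17122 in WT.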
